A study of Rattus norvegicus with 8 samples.

How the data were processed

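Gene expression was measured in primary ventricular cardiomyocytes of newborn Sprague Dawley rats, a culture depleted of fibroblasts by letting these attach to a dish before the remaining cells were plated. Per the labels' protocols, the cells were infected with an adenovirus carrying beta-galactosidase, an inert reporter used as the control, or Flag-tagged histone deacetylase 4 (HDAC4). They were then kept for 48 hours in serum-free medium or in medium with 10 percent fetal calf serum. Each of the 4 groups held 2 samples that the series text calls biological, so 8 arrays were used. Biotin-labelled sense-strand cDNA was hybridised to Affymetrix Gene 1.0 ST arrays, per the labels' protocols.

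The deposited values were linear ratios. Per the submitters' processing notes the arrays were processed with RMA, a method that corrects background, normalises arrays by quantiles and summarises probes. Its version and any genome build are not given in the sources used here. The deposited ratios of 28663 of 29215 probe sets (98.1 percent) had a median of 1 over the 8 arrays within 1e-05, and the other 552 had a median below 1, as a floor under the divisor would give. The values were therefore read as ratios to each probe set's own median; the step and tool that made them are not given in the sources used here. They ran from 0.0351 to 16.4, with 0 missing. Division by the median removes the brightness of a probe set, so a level cannot be set against background and dim probe sets cannot be recognised. The number of arrays limits the precision.

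The design fixed before the data were examined assumed log2 values, so log2 of the ratios was taken first. A planned filter on dim probe sets and a planned choice of the brightest probe set per gene need brightness and were not run. Instead, the log2 values of all probe sets of a gene were averaged. Gene names came from the platform's annotation table, carried by Entrez ID to the RefSeq genes of assembly GRCr8, from which 15279 symbols were taken. In all, 15310 probe sets had 1 symbol, 323 had several and 13582 had none; only the first kind was named, giving 14506 genes, of which 527 had several probe sets. The values of 319 probe sets equalled those of another in every array.

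Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) on all 8 arrays with 4 group means, which left 4 residual degrees of freedom. The contrasts were serum against serum-free medium within each virus, HDAC4 against beta-galactosidase within each medium, the difference between media of the HDAC4 response (the interaction), and both responses averaged. Tests were two-sided, and probe sets or genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Counts of calls are of probe sets unless genes are named, and values of single genes are from the fit of genes. Errors of log2 changes are standard errors of that fit, with 2 arrays on each side, or with all 8 arrays for the interaction. Probe sets were also counted by whether their change was at least 2-fold.

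Named genes were Hdac4, the 10 genes with the largest change in each direction in the serum response of control cells and in the HDAC4 response in each medium, and the 5 in each direction for the interaction. They had to be called, to have a single symbol and, for the first 3 comparisons, arrays that did not overlap between groups. In addition, up to 4 called members with the largest change were taken from each list. The 29 gene lists, written before the data were examined, covered heart muscle, growth, metabolism, stress and the other cell types that a heart digest can hold. The list of MEF2 targets held Bop1, a ribosome biogenesis gene, by mistake; it was left as written, and a test without Bop1 was added after seeing the data. Each was tested in the first 4 contrasts with camera at a preset correlation of 0.01, adjusted over 116 tests, and beside it with camera at an estimated correlation and with fry. Of the 14, 13, 17 and 12 lists that passed for the serum response, the HDAC4 response without and with serum, and the interaction, 0 held with an estimated correlation. With fry, 48 of these 56 kept the call and 8 lost it (adjusted p up to 0.145). Lost were fatty acid oxidation genes in the serum response, and fibroblast markers and FoxO genes with HDAC4 without serum. Cholesterol, matrix and neuronal genes lost it with HDAC4 in serum, and cell cycle and cholesterol genes in the interaction.

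The fit was tested on simulated data with the observed spread of all 29215 probe sets. Each comparison had a single simulated data set, with noise independent between probe sets. In it 67, 67 and 66 probe sets were changed by 0.5, 1 and 2 on the log2 scale. The false share of calls depends on the number of real changes, so it does not carry over to the real calls. For the serum response it recovered 61.2 percent of probe sets changed by 1 on the log2 scale and 95.5 percent of those changed by 2, with 0 false among 106 calls. For the HDAC4 response in serum-free medium the shares were 58.2 and 97.0 percent, with 18 false among 124 calls (14.5 percent). For the HDAC4 response in serum they were 41.8 and 93.9 percent, with 2 false among 92 calls. Changes of 0.5 were recovered in 2.99, 4.48 and 0 percent. Comparisons that share arrays were set beside 20 simulated unchanged data sets.

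Alternatives planned before the data were examined were a term for the sample number, a prior variance with trend and robust estimation, only the groups compared, another quantile normalisation, centring of arrays on their median, and leaving out each array. The trend was fitted over the mean log2 ratio of a probe set, so it is not a trend with brightness. The other quantile normalisation was run on log2 ratios and gave all arrays the same distribution of ratios. Added after seeing the data were 1 value per gene, leaving out the 552 probe sets with a low median, exchanged sample numbers in the HDAC4 group with serum, array weights per group, and leaving out the 2 arrays with the highest first principal component. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.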

Results

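Expression profiles of newborn rat ventricular cardiomyocytes were compared in a 2 by 2 design, in which cells carrying a control (beta-galactosidase) or an HDAC4 adenovirus were kept without or with 10 percent fetal calf serum for 48 hours. HDAC4 is a class IIa histone deacetylase that binds MEF2 transcription factors and represses their targets, and serum is a common hypertrophic stimulus for these cells. Each group held 2 arrays. On the first principal component (48.0 percent of the variance) the 4 control arrays lay at -47.4, -39.3, -20.6 and -22.5, and the 4 HDAC4 arrays at 10.6, 52.7, 46.4 and 20.1. The standard deviation of the log2 difference between the 2 arrays of a group was 0.21 and 0.18 in the control groups without and with serum, but 0.46 and 0.32 in the HDAC4 groups. P-values measure the spread between these few samples pooled over the 4 groups, and not that of the compared groups alone.

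The transcript of the gene that the experimental virus carries was given for every array as a check of the labels. The ratios of Hdac4 were 0.957 and 0.899 in control cells without serum, 1.07 and 1.60 in HDAC4 cells without serum, 0.803 and 0.917 in control cells with serum, and 1.08 and 1.04 in HDAC4 cells with serum. Its log2 change with HDAC4 was 0.49 ± 0.19 (SE) without serum (limma adjusted p = 0.125) and 0.31 ± 0.19 with serum (adjusted p = 0.385), so neither passed the test. Without sample 1 of the serum-free HDAC4 group the change was 0.79 (adjusted p = 0.00356), and without its sample 2 it was 0.20 (adjusted p = 0.309). The species and extent of the viral cDNA are not given in the sources used here, so the rat probe set may not read it.

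**Figure D1:**
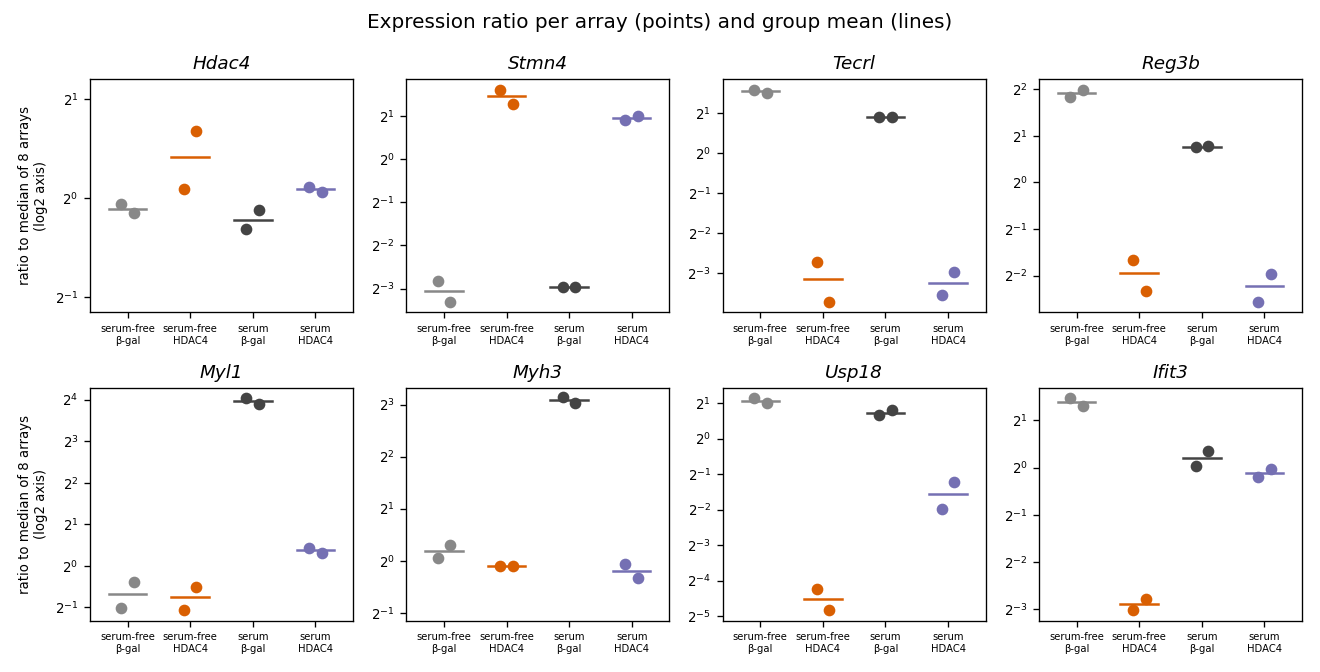
Ratio to the median of the 8 arrays (log2 axis) for 8 genes in the 4 groups named on the horizontal axis; points are single arrays and lines are group means (n = 2). Stmn4 was higher and Tecrl and Reg3b were lower in all HDAC4 arrays, Myl1 and Myh3 were highest in control cells with serum, Usp18 and Ifit3 were lowest in HDAC4 cells without serum, and the Hdac4 change did not pass the test.

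The serum response of control cells asked what the growth medium does without extra HDAC4. Serum raised genes of fast and embryonic skeletal muscle myosin, with Myl1, an alkali light chain, higher by 4.67 ± 0.24 on the log2 scale (25.5-fold, adjusted p = 0.000346) and Myh3, the embryonic heavy chain, by 2.92 ± 0.13. The adhesion genes Selp (P-selectin, 3.23 ± 0.11), Dsc3 (a desmosomal cadherin, 3.02 ± 0.16), Itga2 (2.16 ± 0.14) and Pkp1 (2.15 ± 0.10) rose as well, as did Esm1, Clca4l, Ppef1 and Slc7a3, by 2.47, 2.43, 2.23 and 2.17. The largest falls were those of the complement gene C7 (-3.41 ± 0.20), the growth factor gene Ptn (-3.13 ± 0.24) and the matrix genes Postn (-3.05 ± 0.16), Spon1 (-2.74 ± 0.11) and Aspn (-2.68 ± 0.32). Penk, Pla2g7, Aldoc, Cxcl13 and Igf1 fell by between 2.25 (Igf1) and 2.64 (Penk). In all, 635 probe sets were higher and 523 lower with serum, of which 233 and 192 changed at least 2-fold.

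Among the gene lists, 28 of 36 cell cycle genes rose with serum (33 adjusted over the list alone) and 0 fell, with a median log2 change of 1.12 (camera adjusted p = 1.81e-27, adjusted p = 0.281 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 1.73 ± 0.11, Ccnb1 (cyclin B1) by 1.60 ± 0.10 and Aurka by 1.56 ± 0.14. Of 17 glycolysis genes 10 rose (12 adjusted over the list alone, adjusted p = 0.281 with an estimated correlation). The lactate transporter gene Slc16a3 rose by 1.41 ± 0.09 and Pfkl by 1.05 ± 0.09. The fetal and hypertrophic list had 6 of 16 members higher (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Its largest rise was that of the smooth muscle gene Cnn1 (1.53 ± 0.09). Cholesterol synthesis genes fell in 13 of 20 cases (18 adjusted over the list alone). Their median was -0.66 (camera adjusted p = 3.28e-16, adjusted p = 0.281 with an estimated correlation). Tm7sf2 changed by -1.58 ± 0.12 and Fdft1, squalene synthase, by -0.94 ± 0.11. In the fatty acid synthesis list 6 of 14 genes fell (8 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). The desaturase gene Scd changed by -1.24 ± 0.13. Fatty acid oxidation genes fell in 4 cases and rose in 1 of 28 (5 and 1 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation and 0.0621 with fry). Acsl1, which activates fatty acids, changed by -1.40 ± 0.14 and Cpt1a by -0.96 ± 0.11.

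Serum also lowered 18 of 30 interferon and antiviral genes in control cells (23 lower and 1 higher adjusted over the list alone, median -0.74, adjusted p = 0.281 with an estimated correlation). Mx1, an antiviral GTPase, changed by -2.17 ± 0.21. The FoxO and atrophy list had 7 of 22 genes lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation). The muscle ubiquitin ligase gene Fbxo32 changed by -1.83 ± 0.21 and Pik3ip1 by -1.22 ± 0.11. Calcium handling and ion channel genes were lower in 4 of 25 cases (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.281 with an estimated correlation). The potassium channel gene Kcnd3 changed by -1.37 ± 0.15. Smaller shifts upwards passed for SRF and actin cytoskeleton genes (3 of 22 rose, 8 adjusted over the list alone, adjusted p = 0.281 with an estimated correlation) and nucleolar genes (3 of 21 rose, 8 adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). Of 15 NRF2 genes 2 rose (2 adjusted over the list alone, adjusted p = 0.569 with an estimated correlation), and the heme oxygenase gene Hmox1 rose by 1.13 ± 0.11.

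Markers of other heart cells moved with serum in opposite directions. Of 19 fibroblast markers 9 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.47, adjusted p = 0.299 with an estimated correlation). The fibroblast receptor gene Pdgfra changed by -1.87 ± 0.12, Fbln1 by -1.69 ± 0.12 and Tcf21 by -1.56 ± 0.09. Of 16 endothelial markers 7 rose (9 adjusted over the list alone, median 0.40, adjusted p = 0.281 with an estimated correlation). The VEGF receptor gene Flt1 rose by 1.09 ± 0.10. Macrophage markers did not pass as a list (median -0.05, adjusted p = 0.314), and sarcomere genes did not either (median 0.08, adjusted p = 0.121). Of the macrophage markers Cd163, Lyz2, Ptprc and Mrc1 were called singly, each losing the call without at least 1 array. The count of 1158 probe sets became 60 or 106 without sample 1 or 2 of the serum-free control group, 56 or 70 without sample 1 or 2 of the control group with serum, 2292 without 1 of the serum-free HDAC4 samples (either) and 734 without 1 of the HDAC4 samples (either) with serum. It became 3786 (1801 higher and 1985 lower, a turned balance) without the 2 arrays with the highest first principal component (1 of each HDAC4 group), an alternative added after seeing the data, and equally with only the compared groups in the fit, chosen before, which for this comparison is the same fit. The balance also turned to 31 higher and 39 lower without sample 2 of the control group with serum. Array weights, added after seeing the data, gave 2625 and 2901, and all 20 of the largest genes above remained called without any 1 array.

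The HDAC4 response in serum-free medium asked what HDAC4 does to unstimulated cells. The largest falls were in interferon-induced genes: Usp18, whose product removes the ubiquitin-like protein ISG15, changed by -5.60 ± 0.28 (48.6-fold lower, adjusted p = 9.27e-05), Mx2 by -4.81 ± 0.24, Rtp4 by -4.52 ± 0.21, Rsad2 by -4.35 ± 0.25, Ifit3 by -4.29 ± 0.15, Oas1a by -4.28 ± 0.26, Mx1 by -4.09 ± 0.21 and Isg15 by -4.08 ± 0.11. Tecrl, a reductase-like gene of heart muscle, fell as well (-4.77 ± 0.32), and Reg3b changed by -3.90 ± 0.26. The largest rise was that of Stmn4, a stathmin family gene known from neurons (4.51 ± 0.18, 22.8-fold). Serinc2, Noct, Rassf1, Pvr, Nes (the intermediate filament nestin), Abhd2, Epha2, Efhd2 and Hr rose by between 1.87 (Hr) and 2.22 (Serinc2). In all, 1200 probe sets were higher and 1684 lower, and at least 2-fold changes were found in 298 and 677.

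Interferon and antiviral genes fell in 28 of 30 cases (29 adjusted over the list alone). Their median was -2.56 (camera adjusted p = 8.11e-32, adjusted p = 0.238 with an estimated correlation). Inflammatory and NF-kB genes fell in 9 of 19 cases (12 lower and 1 higher adjusted over the list alone, adjusted p = 0.281 with an estimated correlation). The adhesion gene Vcam1 changed by -2.59 ± 0.16, the chemokine gene Ccl7 by -1.82 ± 0.17 and Il6 by -1.48 ± 0.15. Macrophage and leukocyte markers had a median of 0.02 and did not pass as a list (adjusted p = 0.928). C1qa, Ptprc, C1qc and Mrc1 of that list were called singly, each losing the call without at least 1 array.

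Of 19 sarcomere genes 17 fell (17 adjusted over the list alone). Their median was -1.05 (camera adjusted p = 4.33e-14, adjusted p = 0.281 with an estimated correlation). The largest falls in the list were those of the Z-disc gene Ldb3 (-2.22 ± 0.10), Myom1 of the M-band (-2.12 ± 0.22), Myoz2 (-1.82 ± 0.11) and Mybpc3, cardiac myosin binding protein C (-1.80 ± 0.09). Calcium handling and ion channel genes fell in 17 of 25 cases (19 lower and 1 higher adjusted over the list alone, median -0.92, adjusted p = 0.238 with an estimated correlation). The potassium channel gene Kcnj3 changed by -2.21 ± 0.09, phospholamban (Pln) by -2.16 ± 0.16, triadin (Trdn) by -2.11 ± 0.14 and the ryanodine receptor gene Ryr2 by -1.90 ± 0.18. Genes of the list of MEF2 targets in muscle fell in 16 and rose in 2 of 25 cases (18 and 2 adjusted over the list alone, median -0.96, adjusted p = 0.281 with an estimated correlation). The ribosome biogenesis gene Bop1 was in this list by mistake, and without it, a test added after seeing the data, 16 of 24 genes fell and 1 rose (camera adjusted p = 7.47e-10, adjusted p = 0.254 with an estimated correlation). The mitochondrial coactivator gene Ppargc1a changed by -3.15 ± 0.16 and the insulin-responsive glucose transporter gene Slc2a4 by -2.16 ± 0.14. The fetal and hypertrophic list held 10 genes that fell and 4 that rose among 16 (10 and 4 adjusted over the list alone, median -0.58, adjusted p = 0.299 with an estimated correlation): Myh7, the slow myosin heavy chain, changed by -0.96 ± 0.08 and Nppb by -0.95 ± 0.10, whereas Cnn1 rose by 1.75 ± 0.09.

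Respiratory chain genes fell in 25 of 25 cases (25 adjusted over the list alone, median -0.66, camera adjusted p = 1.61e-15, adjusted p = 0.281 with an estimated correlation). Cox8b changed by -1.19 ± 0.15 and Ndufs3 by -1.15 ± 0.10. Fatty acid oxidation genes fell in 14 and rose in 3 of 28 cases (16 and 3 adjusted over the list alone, adjusted p = 0.415 with an estimated correlation). Besides Ppargc1a, which this list shares, the carnitine transferase gene Cpt1b changed by -2.46 ± 0.19 and Hadh by -2.04 ± 0.19. In the FoxO and atrophy list 9 of 22 genes fell and 4 rose (10 and 5 adjusted over the list alone, adjusted p = 0.720 with an estimated correlation). The ubiquitin ligase genes Fbxo32 and Trim63 changed by -2.24 ± 0.21 and -1.57 ± 0.12, and Bcl6 rose by 1.09 ± 0.10. This list did not pass without sample 2 of the serum-free HDAC4 group (adjusted p = 0.182).

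Cell cycle genes were higher in 32 of 36 cases (33 adjusted over the list alone, median 1.25, camera adjusted p = 1.40e-18, adjusted p = 0.284 with an estimated correlation). The replication genes Mcm5 and Cdc6 rose by 1.86 ± 0.09 and 1.76 ± 0.10, and Ccnb1 by 1.72 ± 0.10. Nucleolar genes rose in 14 of 21 cases (14 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). Bop1 rose by 0.91 ± 0.13 and Nolc1 by 0.90 ± 0.11. Immediate early genes rose in 12 and fell in 6 of 28 cases (16 and 7 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation): Klf6 rose by 1.18 ± 0.10, while the nuclear receptor gene Nr4a1 changed by -1.69 ± 0.08. That list did not pass without sample 1 of the serum-free HDAC4 group (adjusted p = 0.121).

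Fibroblast markers were lower beside these heart muscle genes, 6 of 19 falling and 1 rising (6 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.0197, adjusted p = 0.590 with an estimated correlation), but the list did not pass without sample 2 of the serum-free HDAC4 group (adjusted p = 0.129). Endothelial and smooth muscle markers had medians of -0.11 and -0.02 and did not pass. The 2 HDAC4 arrays of this group stood farther apart than those of any other, and 14.5 percent of the calls on simulated data were false. Few probe sets were changed in that simulation and their noise was independent, so this share does not measure the false share of the real calls. The count of 2884 probe sets became 851 or 954 without sample 1 or 2 of the control group, 9019 without sample 1 of the HDAC4 group and 1701 without 1 of the control samples (either) with serum. It became 750 with only the compared groups in the fit and 1718 with array weights, the latter added after seeing the data. The excess of lower probe sets turned to 5068 higher and 3951 lower without sample 1 of the HDAC4 group, 1408 and 1381 without its sample 2, and 2063 and 2000 without the 2 arrays with the highest first principal component, added after seeing the data.

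**Figure D2:**
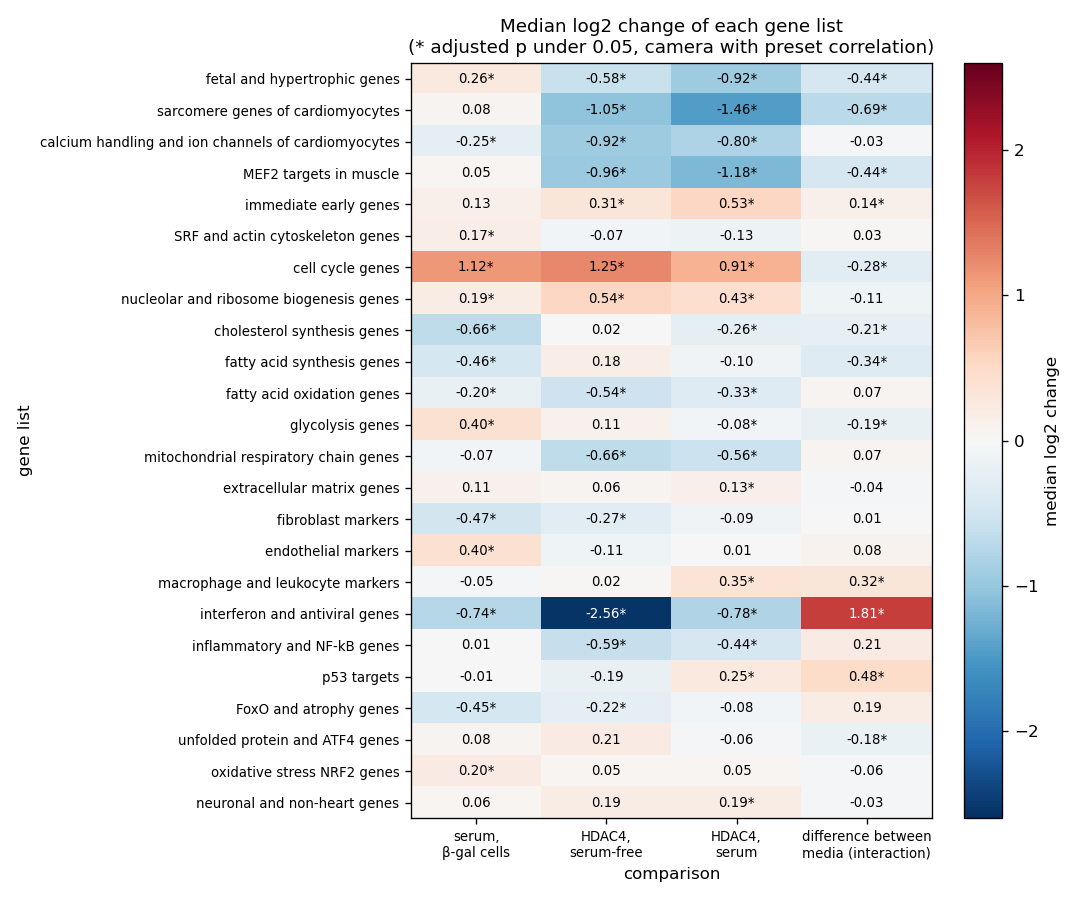
Median log2 change of the members of 24 gene lists (vertical axis) in 4 comparisons (horizontal axis), coloured from blue (lower) to red (higher); a star marks an adjusted p under 0.05 by camera with a preset correlation. Of the medians drawn, interferon genes had the lowest, -2.56 with HDAC4 in serum-free medium, and the highest, 1.81 in the interaction; cell cycle genes lay at 1.12, 1.25 and 0.91 in the first 3 comparisons.

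With serum, the HDAC4 response asked how HDAC4 alters stimulated cells. Tecrl had the largest fall (-4.15 ± 0.32, 17.8-fold lower, adjusted p = 0.000376), followed by Myl1 (-3.60 ± 0.24) and Myh3 (-3.29 ± 0.13), which serum had raised in control cells. Rxfp1 (-3.26 ± 0.17), the membrane repair gene Trim72 (-3.12 ± 0.15), the muscle laminin receptor gene Itga7 (-3.11 ± 0.09), Snap91 (-3.07 ± 0.11), the cardiac kinase gene Tnni3k (-3.05 ± 0.15), Reg3b (-3.02 ± 0.26) and the sodium channel gene Scn3b (-3.02 ± 0.20) fell as well. Stmn4 rose by 3.91 ± 0.18, the tight junction gene Cldn4 by 2.86 ± 0.10, the neurofilament gene Nefm by 2.23 ± 0.17 and Egr1, an immediate early transcription factor gene, by 2.14 ± 0.09. Fmo5, Dpp4, Pttg1 (securin), Rassf1, Atf3 and Gadd45a rose by between 1.63 (Gadd45a) and 1.92 (Fmo5). In all, 748 probe sets were higher and 1273 lower, and at least 2-fold changes were found in 164 and 544.

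All 19 sarcomere genes fell (19 adjusted over the list alone, median -1.46, camera adjusted p = 7.09e-26, adjusted p = 0.238 with an estimated correlation). Mybpc3 changed by -3.00 ± 0.09, Myom1 by -2.82 ± 0.22 and Ldb3 by -2.65 ± 0.10. The MEF2 list had 19 of 25 genes lower and 2 higher (19 and 3 adjusted over the list alone, median -1.18, adjusted p = 0.238 with an estimated correlation), and without Bop1 19 of 24 lower and 2 higher (camera adjusted p = 3.56e-14, adjusted p = 0.217 with an estimated correlation). Ppargc1a changed by -2.89 ± 0.16 and the small heat shock gene Hspb7 by -2.81 ± 0.22. Calcium handling and ion channel genes fell in 16 of 25 cases (20 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). Ryr2 changed by -2.49 ± 0.18, the potassium channel gene Kcnq1 by -2.11 ± 0.11 and Pln by -2.04 ± 0.16. The fetal and hypertrophic list had 10 of 16 genes lower and 3 higher (12 and 3 adjusted over the list alone, median -0.92, adjusted p = 0.238 with an estimated correlation). Myh7 changed by -2.67 ± 0.08, Fhl1 by -1.61 ± 0.08 and Nppb, a natriuretic peptide gene, by -1.37 ± 0.10.

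Respiratory chain genes fell in 21 of 25 cases (25 adjusted over the list alone, median -0.56, adjusted p = 0.281 with an estimated correlation). Cox8b changed by -1.29 ± 0.15. Fatty acid oxidation genes fell in 11 and rose in 4 of 28 cases (14 and 4 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation). The fatty acid binding protein gene Fabp3 changed by -2.67 ± 0.13 and Cpt1b by -2.56 ± 0.19. Of 17 glycolysis genes 4 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation). The muscle phosphofructokinase gene Pfkm changed by -1.47 ± 0.12 and Slc16a3 by -1.06 ± 0.09, and Pfkfb3 rose by 0.97 ± 0.11. Cholesterol synthesis genes fell in 6 and rose in 1 of 20 cases (7 and 1 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation), a list call lost after another quantile normalisation (adjusted p = 0.596).

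Immediate early genes rose in 18 and fell in 2 of 28 cases (19 and 3 adjusted over the list alone, median 0.53, camera adjusted p = 8.87e-08, adjusted p = 0.277 with an estimated correlation). Atf3 rose by 1.86 ± 0.09 and Egr2 by 1.40 ± 0.13, and the phosphatase gene Dusp4 changed by -1.89 ± 0.10. Cell cycle genes rose in 24 of 36 cases (30 adjusted over the list alone, median 0.91, adjusted p = 0.299 with an estimated correlation). Ccnb1 rose by 1.43 ± 0.10 and Birc5 (survivin) by 1.37 ± 0.10. Nucleolar genes rose in 11 of 21 cases (16 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). Targets of p53 rose in 6 and fell in 1 of 17 cases (7 and 1 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). Gadd45a rose by 1.63 ± 0.11, Pmaip1 by 1.41 ± 0.12 and Mdm2, which limits p53, by 0.73 ± 0.08. Interferon genes fell in 15 and rose in 2 of 30 cases (19 and 2 adjusted over the list alone, median -0.78, adjusted p = 0.299 with an estimated correlation). Oas1a changed by -2.38 ± 0.26, Usp18 by -2.34 ± 0.28 and Bst2 by -1.38 ± 0.12. Inflammatory and NF-kB genes fell in 8 and rose in 1 of 19 cases (12 and 2 adjusted over the list alone, adjusted p = 0.281 with an estimated correlation). Il6 changed by -2.09 ± 0.15 and Ccl20 by -1.54 ± 0.14.

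Macrophage and leukocyte markers were higher beside these changes, with 5 of 20 rising (11 adjusted over the list alone, median 0.35, camera adjusted p = 3.57e-05, adjusted p = 0.30 with an estimated correlation). The scavenger receptor gene Mrc1 rose by 0.64 ± 0.11, a call lost without 3 of the arrays, each left out alone. The calls of Coro1a, Laptm5 and C1qc were lost without 4, 6 and 6 of the arrays in the same way. Fibroblast markers fell in 6 and rose in 1 of 19 cases (7 and 3 adjusted over the list alone), with decorin (Dcn) at -1.32 ± 0.15 and Fmod at -1.27 ± 0.16, but did not pass as a list (adjusted p = 0.121). Extracellular matrix genes (3 of 28 higher and 2 lower, 4 and 2 adjusted over the list alone, adjusted p = 0.660 with an estimated correlation) did not pass without sample 2 of the HDAC4 group (adjusted p = 0.170). Of 17 neuronal genes 2, Nefm and Nefl (1.26 ± 0.15), rose (2 adjusted over the list alone, adjusted p = 0.660 with an estimated correlation). That list did not pass without sample 1 of the HDAC4 group (adjusted p = 0.0706). The count of 2021 probe sets became 532 or 509 without sample 1 or 2 of the control group, 743 or 837 without sample 1 or 2 of the HDAC4 group, 1106 without 1 of the serum-free control samples (either) and 3307 without 1 of the serum-free HDAC4 samples (either). It became 3206 without the 2 arrays with the highest first principal component (1 of each HDAC4 group), added after seeing the data.

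The interaction tested whether the HDAC4 response differed between media. It did so in 57 probe sets with a higher and 48 with a lower response in serum. Interferon genes led the first kind: the HDAC4 response was higher in serum by 3.97 ± 0.21 for Ifit3 (adjusted p = 0.00250), 3.90 ± 0.36 for Rsad2, 3.47 ± 0.20 for Oasl, 3.37 ± 0.34 for Mx2 and 3.27 ± 0.39 for Usp18. Skeletal muscle genes led the second kind, with differences of -3.51 ± 0.34 for Myl1 and -3.00 ± 0.18 for Myh3, followed by the amino acid transporter gene Slc7a3 (-2.30 ± 0.18), the pericyte proteoglycan gene Cspg4 (-1.87 ± 0.12) and Mybpc2 (-1.71 ± 0.18).

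As a list, interferon and antiviral genes had a response higher in serum in 20 of 30 cases (29 adjusted over the list alone, median 1.81, camera adjusted p = 2.45e-46, adjusted p = 0.238 with an estimated correlation). Sarcomere genes had a lower one in 5 of 19 cases (14 adjusted over the list alone, median -0.69, camera adjusted p = 2.42e-16, adjusted p = 0.277 with an estimated correlation). For Csrp3 the difference was -1.33 ± 0.14 and for Mybpc3 -1.19 ± 0.13. The same direction was found for 4 of 16 fetal and hypertrophic genes (9 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). Myh7 differed by -1.71 ± 0.12. Of 25 genes in the MEF2 list 3 had a lower response in serum (12 lower and 4 higher adjusted over the list alone, adjusted p = 0.341 with an estimated correlation), and without Bop1 3 of 24 (11 lower and 4 higher adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). Of 36 cell cycle genes 4 had a lower response in serum (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.490 with an estimated correlation). Cdc6 differed by -1.40 ± 0.14 and Mcm5 by -1.33 ± 0.13. Glycolysis genes had a lower response in 3 of 17 cases (5 adjusted over the list alone, adjusted p = 0.308 with an estimated correlation), and Slc16a3 differed by -1.63 ± 0.13. Immediate early genes had a higher response in 3 and a lower one in 1 of 28 cases (7 and 3 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). The difference was 1.45 ± 0.17 for Fos and 1.23 ± 0.12 for Egr1. The members named here by their lists each lost the call without at least 1 array, for example Csrp3 (adjusted p = 0.128) and Mcm5 (adjusted p = 0.110) without sample 1 of the serum-free control group. Among p53 targets 1 of 17, Perp, passed (1.03 ± 0.16, 7 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation), but not without sample 1 of the control group with serum (adjusted p = 0.254).

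Lists shifted without a called gene among cholesterol synthesis genes (median -0.21, 3 lower adjusted over the list alone, adjusted p = 0.504 with an estimated correlation), fatty acid synthesis genes (median -0.34, 6 lower and 1 higher adjusted over the list alone, adjusted p = 0.458 with an estimated correlation) and macrophage markers (median 0.32, 0 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). In limma's fit the lowest adjusted p among the first and the last was that of Insig1 (-0.75 ± 0.13, adjusted p = 0.0528) and of Fcer1g (0.82 ± 0.20, adjusted p = 0.129). Unfolded protein and ATF4 genes had a lower response in 2 and a higher one in 1 of 27 cases (7 and 1 adjusted over the list alone, median -0.18, adjusted p = 0.458 with an estimated correlation). Ddit3 differed by 1.24 ± 0.18, a call lost without sample 1 of the control group with serum (adjusted p = 0.228). Another quantile normalisation turned the share of higher responses from 54.3 to 44.3 percent of the calls, ended the call of the fatty acid synthesis list (adjusted p = 0.445) and reversed the cholesterol list (adjusted p = 0.919). It gave the log2 ratios of all arrays the same distribution, although their standard deviations ran from 0.226 to 0.446 before. The trend used below was fitted over mean log2 ratios and not over brightness. Without sample 1 of the serum-free HDAC4 group the cell cycle, cholesterol and ATF4 lists did not pass (adjusted p = 0.0599, 0.114 and 0.142). The count of 105 probe sets became 0 in limma without sample 1 or 2 of the serum-free control group or sample 1 of the control group with serum (1423, 1645 and 1399 at an unadjusted p under 0.05), 3 without the latter's sample 2, 9 without 1 of the HDAC4 samples (either) with serum and 223 without sample 1 of the serum-free HDAC4 group. It became 26 with trend and robust estimation (19 higher and 7 lower) and, both added after seeing the data, 64 without the 2 arrays with the highest first principal component (1 of each HDAC4 group) and 187 with 1 value per gene. With 1 value per gene 73 were higher and 114 lower, and without sample 2 of the serum-free HDAC4 group 47 and 50, which turned the balance. Of the 10 genes with the largest differences, Ifit3, Oasl and Myh3 remained called whichever array was left out. The other 7 each lost the call without at least 1 array, with Usp18 at the highest adjusted p (0.142, without sample 1 of the serum-free control group).

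Whether HDAC4 opposed serum was asked over all probe sets. Of the 635 probe sets that serum raised in control cells, HDAC4 lowered 127 in serum, where independent lists would share 27.7, and raised 179, where they would share 16.3. Of the 523 that serum lowered, HDAC4 raised 29 (13.4 for independent lists) and lowered 103 (22.8). Together 156 calls were opposite and 282 alike; unchanged simulated groups sharing the same control arrays gave 0 of either, but without real changes almost nothing is called, so this 0 does not measure how far the shared arrays add to the calls. The log2 changes of these comparisons had a correlation of 0.0132 across probe sets, which are not independent replicates. This stood beside -0.320 in the simulation, and a covariance of 0.00172 beside -0.00640. Both comparisons use the control arrays with serum, so their calls are not independent. The opposite calls became 12 to 23 without any 1 of the 4 control arrays, 67 or 72 without sample 1 or 2 of the HDAC4 group with serum and 364 without 1 of the serum-free HDAC4 samples (either).

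Averaged over media, HDAC4 raised 2023 and lowered 2535 probe sets; averaged over viruses, serum raised 1195 and lowered 1133. The averaged responses had a correlation of 0.153 across probe sets and a covariance of 0.0169, beside -0.244 and -0.00463 in the simulation, and 829 calls were alike and 335 opposite. Without sample 1 of the serum-free HDAC4 group the correlation was -0.0890. The HDAC4 responses without and with serum, which share no arrays, had a correlation of 0.695, with 1384 calls alike and 8 opposite. In HDAC4 cells serum raised 560 and lowered 486 probe sets (53.5 percent higher, against 65.7 percent after another quantile normalisation), and 440 of its calls were alike and 21 opposite to those in control cells. Usp18, at -0.34 ± 0.28 with serum in control cells (adjusted p = 0.609), rose by 2.93 ± 0.28 with serum in HDAC4 cells, and Myl1 rose by 1.16 ± 0.24. The count of 1046 in HDAC4 cells became 362 without 1 of the serum-free control samples (either) and 311 without 1 of the control samples (either) with serum. It became 178 or 120 without sample 1 or 2 of the HDAC4 group with serum and 2599 without sample 1 of the serum-free HDAC4 group. With only the compared groups in the fit it became 0 in limma (2359 at an unadjusted p under 0.05), and with array weights, added after seeing the data, 225. Its balance turned to 498 higher and 612 lower without sample 2 of the serum-free HDAC4 group, and to 49 and 71 without sample 2 of the HDAC4 group with serum. The averaged HDAC4 count of 4558 became 2392 or 2487 without sample 1 or 2 of the serum-free control group and 2312 or 2270 without sample 1 or 2 of the control group with serum. It became 2929 without sample 1 of the HDAC4 group with serum and 10411 without sample 1 of the serum-free HDAC4 group, where the balance turned to 6114 higher and 4297 lower. It also turned without that group's sample 2 (2563 and 2559) and without the 2 arrays with the highest first principal component (3333 and 2860), added after seeing the data. The serum response averaged over viruses became 751 or 898 probe sets without sample 1 or 2 of the serum-free control group, 686 or 729 without sample 1 or 2 of the control group with serum, 1171 or 1209 without sample 1 or 2 of the HDAC4 group with serum, and 3907 without sample 1 of the serum-free HDAC4 group. Its balance turned to 1507 higher and 1981 lower without sample 2 of that group, and to 1829 and 2149 without the 2 arrays with the highest first principal component.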

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

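The tests of leukocytes, of the share of cardiomyocytes, of single arrays standing apart and of HDAC4 strength were chosen after the results they bear on, or closely related values, had been seen. The results given here are those whose HDAC4 response differed between serum-free medium and serum by the interaction test, which is a difference between groups. On the log2 scale the response in serum was higher by 3.97 for Ifit3, 3.90 for Rsad2, 3.47 for Oasl, 3.37 for Mx2 and 3.27 for Usp18, which are interferon-induced genes. It differed by -3.51 for Myl1, -3.00 for Myh3, -2.30 for Slc7a3, -1.87 for Cspg4 and -1.71 for Mybpc2. The median difference was 1.81 for interferon and antiviral genes, 0.48 for p53 targets, 0.32 for macrophage and leukocyte markers and 0.14 for immediate early genes. It was -0.69 for sarcomere genes, -0.44 for both fetal and hypertrophic genes and the MEF2 list, -0.34 for fatty acid synthesis genes and -0.28 for cell cycle genes. It was -0.21 for cholesterol synthesis genes, -0.19 for glycolysis genes and -0.18 for unfolded protein and ATF4 genes. Of these 12 lists 0 held with an estimated correlation, and the cholesterol list turned after another quantile normalisation (adjusted p = 0.919).

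Interferon and antiviral genes were lower with HDAC4 in serum-free medium, with a median of -2.56. Fewer leukocytes in the HDAC4 cultures would lower leukocyte markers as well. Some macrophage and leukocyte markers were called singly, but the median of that list was 0.02. It lay 2.58 above that of the interferon genes (permutation p = 9e-05 over the genes of both lists, which are not independent). The interferon list had the lowest median of the lists drawn, and the test was chosen after that was seen, so this p adds little. One array standing apart is argued against by the medians without either serum-free HDAC4 sample, of which the one nearer 0 was -2.38. A difference in dose or preparation between the viruses cannot be told apart from an effect of HDAC4, because 0 probe sets were annotated to an adenoviral or reporter gene and each virus was used in its own groups. An effect of HDAC4 on interferon-induced genes therefore stays open beside that difference.

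Sarcomere genes were lower with HDAC4 in both media. A lower share of cardiomyocytes alone would raise the markers of every other cell type alike. On average over media, fibroblast markers changed by -0.29, smooth muscle and pericyte markers by -0.14, endothelial markers by -0.06 and macrophage markers by 0.18. This range of 0.477 among 4 marker lists gave an exact permutation p = 0.0286, the smallest that the 70 splits of 4 against 4 arrays can give, with the highest and lowest list chosen anew in each split. Each array was taken relative to the mean of its medium, which shrinks the range in splits unequal over media. The p is therefore too small, and the test cannot decide. A lower share of cardiomyocytes beside a shift among the other cell types is not excluded either. HDAC4 arrays standing apart from their partner are argued against by the sarcomere median without any 1 of them, which was -0.91 where it lay nearest 0. A difference in dose or preparation between the viruses cannot be told apart here either, because each virus was used in its own groups. A lower expression of sarcomere genes in the cardiomyocytes themselves stays open beside that difference and a lower share of cardiomyocytes. It is a hypothesis found and examined on the same arrays.

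The 2 HDAC4 arrays of each medium lay far apart, and their pair differences in the media were correlated at -0.690 over probe sets. Unequal HDAC4 strength between cultures would separate genes that were higher and lower with HDAC4 in the other medium, but it cannot be told apart from other sources, because the largest separation lay between the bounds set for either reading. At bounds of 0.5 to 2 on their mean log2 change it ran from -0.04 to 0.209 in the serum-free pair, the latter with only 4 higher genes (0.06 with 701 higher and 1187 lower genes at 0.5), and from -0.19 to -0.08 in the serum pair (-0.15 with 1145 and 1522 genes at 0.5), and Hdac4 itself read 1.07 and 1.60 in the first and 1.08 and 1.04 in the second. Signal variation that reaches genes not expressed in heart cells cannot be told apart from other sources either, because over 1240 olfactory and vomeronasal receptor genes the correlation was -0.342, between the bounds set for either reading. Over the other genes it was -0.759. Of the receptor genes 19 were called higher and 1 lower with HDAC4 without serum, and 5 and 3 with serum. Among all 14506 genes these counts were 1156 and 1546 without serum, and 792 and 1196 with serum. The median difference of sample 2 from sample 1 over the receptor genes was 0.233 in the serum-free HDAC4 pair and -0.119 in the serum pair. Over all probe sets these medians were 0.024 and -0.016.

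With 4 HDAC4 arrays against 4 control arrays and no term for the medium, 2531 probe sets were called. Only 1 of the 35 splits of the arrays, the real one, gave as many, against 403 in the highest other. This share is under 0.05 but is the smallest that 35 splits can give, so it cannot exclude chance. It also does not part HDAC4 from the virus preparation. With 4 arrays with serum against 4 without and no term for the virus, 403 probe sets were called, and 2 of the 35 splits gave as many, a share not under 0.05, so chance is not excluded by this share. The highest other split, with 2531, is the split by virus, a structure of the samples and not a random grouping. The remaining 33 splits gave 0 in limma.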

How the results depend on the processing

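Array weights, 1 value per gene, exchanged sample numbers, the MEF2 list without Bop1 and the joint removal of the 2 HDAC4 arrays with the highest first principal component were chosen after seeing the data. The cause of the moves below was not tested. There were 6717 values of 399 results, each a named gene in 1 comparison, under up to 17 alternatives. Of these, 5776 kept their side of the threshold, 897 lost the call, 0 turned and the others gained a call. A change of direction was counted only where the gene was called in either fit. Of 787 values for 56 passed lists, 709 kept direction and call, 77 lost the call and 1 turned, 56 of the losses being those with an estimated correlation. The planned filter on dim probe sets and the choice of the brightest probe set could not be run, since the ratios keep no signal over background.

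With the replicate block, a paired analysis by sample number, the counts were 477 for serum in control cells (1158 without it), 1782 and 1136 for HDAC4 without and with serum (2884, 2021), 3 for the interaction (105), 377 for serum in HDAC4 cells (1046), 1280 for serum averaged (2328) and 70 opposite calls (156). The labels do not say that equal numbers are paired, and pair differences correlated at -0.690 between the HDAC4 groups and 0.272 between the serum-free groups, and at -0.336 between the serum-free control and the serum HDAC4 group. With exchanged numbers the interaction count was 52, and serum averaged had 1271 higher and 1292 lower.

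Another quantile normalisation gave 2142 for serum in control cells, 3035 for HDAC4 in serum, 503 opposite calls and an adjusted p = 0.919 in the other direction for cholesterol genes in the interaction. It was run on the log2 ratios and made their spread equal in all arrays, so it does not repeat a normalisation of intensities. Trend and robust estimation, with a trend over mean log2 ratios and not brightness, gave 26 for the interaction and 96 opposite calls. With 1 value per gene the interaction count was 187. Array weights gave 5526 for serum in control cells, 1718 and 3230 for HDAC4 without and with serum, 50 for the interaction, 225 for serum in HDAC4 cells and 630 opposite calls. Without these 2 HDAC4 arrays together the counts were 3786 for serum in control cells, 3206 for HDAC4 in serum, 64 for the interaction, 3978 for serum averaged and 491 opposite calls. Only the 2 groups compared gave 3786 for serum in control cells, 750 for HDAC4 without serum and, for serum in HDAC4 cells, 0 in limma (2359 at an unadjusted p under 0.05).

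Leaving out each array assumes that a lone sample varies like the other groups. Counts then ran from 56 to 2292 for serum in control cells, 851 to 9019 and 509 to 3307 for HDAC4 without and with serum, and 120 to 2599 for serum in HDAC4 cells. For the interaction they ran from 0 in limma (1423 at an unadjusted p under 0.05, without sample 1 of the serum-free control group) to 223. They ran from 2270 to 10411 for HDAC4 averaged, 686 to 3907 for serum averaged and 12 to 364 for opposite calls. The correlation of the averaged responses ran from -0.0890 to 0.268, and the Hdac4 change without serum from 0.20 to 0.79, the latter past the threshold.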

Other observations

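Genes of class IIa deacetylases, MEF2 factors and their partners did not pass as a list in any of the 4 comparisons tested, with camera adjusted p = 0.539 and 0.216 for HDAC4 without and with serum. Within that list Hdac5, another class IIa deacetylase gene, changed by -1.33 ± 0.09 (SE) with HDAC4 without serum and by -1.15 ± 0.09 with serum. Smooth muscle and pericyte, epicardial, red blood cell and glucocorticoid-induced genes did not pass in any of the 4 comparisons either. Their lowest camera adjusted p was 0.0608, for smooth muscle and pericyte markers with HDAC4 in serum, 0.409, for epicardial markers in the serum response, 0.0535, for red blood cell markers with HDAC4 without serum, and 0.0590, for glucocorticoid-induced genes in the serum response. In the serum response of control cells, extracellular matrix genes had a median of 0.11 and a mean of -0.13, which differ in sign, and the list did not pass (camera adjusted p = 0.855).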
